A study of Bacillus subtilis with 6 samples.

How the data were processed

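Whole genome sequencing of genomic DNA was analysed in 6 libraries of *B. subtilis* PY79, 3 overexpressing *ccrZ* and 3 overexpressing *ccrZ*-D166A from a xylose-inducible promoter in cells without the native gene. Groups and replicate numbers were taken from the genotype and replicate labels. The deposited values are raw read counts per bin of 1000 bases, not normalised, along a sequence named PY79, per the file headers. BWA, SAMtools and bedtools are named per the submitters' processing notes; versions, parameters, the accession of the sequence and the treatment of duplicate reads are not given in the sources used here. The deposited table carries the tag q20, which may stand for a minimum mapping quality of 20, though no source used here says so. Such a filter would lower counts in repeated sequences, which bears on bins that are empty or low in every library. The table covers 4034 bins, of which the last holds 459 bases, and counts in it were scaled to 1000 bases for profiles. A second deposited table held the same 4034 rows of counts and was not used.

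Total counts per library ran from 932555 to 1286983. Replicates of a group were compared by a chi-square test of their counts. Over bins the value per degree of freedom was 1.13, 1.03 and 1.21 for the ccrZ pairs and 0.901, 0.921 and 0.951 for the ccrZ-D166A pairs. Over 100 kb windows it was 1.68 for ccrZ-D166A replicates 1 and 2 and between 6.54 and 39.7 for the other pairs. Replicates therefore differed in their profiles, and all 6 libraries were kept separate; ccrZ-D166A replicates 1 and 2 summed as 1 library was added as an alternative. Stated precision covers counting error only where it comes from counts, since reads copied in library preparation are not independent molecules.

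The origin was set at the first base of the sequence and distances were circular. The terminus was the minimum of a running median over 101 kb of the profile summed over all libraries after scaling each to its total, found without reference to groups. The origin-to-terminus ratio is the median count per bin within 50 kb of the origin over that within 50 kb of the terminus. Arm slopes are least squares fits of log2 count per bin on distance, with bins of at least 10 counts in at least 3 libraries. These values were compared by two-sided exact permutation tests over 20 assignments. Counts in 100 kb windows and in single bins were tested with edgeR's quasi-likelihood test and TMM factors, and local changes with the same test and a running median over 51 bins as offset. P-values were adjusted by Benjamini-Hochberg, with a threshold of 0.05. Segment slopes were tested with limma. The software was R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

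The text names, by a rule fixed before the data were examined, the origin and terminus windows, the 3 windows of 100 kb and the 3 called bins with the largest log2 change in each direction, and up to 10 runs of called local bins per direction. The comparisons, their tests and most alternatives were fixed at the same time: other window widths, the mean in place of the median, a terminus opposite the origin, Theil-Sen slopes on 10 kb means, arm ends of 200 kb left out, bins between 0.5 and 1.5 times their local level only, median-of-ratios, total-count and terminus scaling, DESeq2, no filter, sums of 5 and 10 bins, running medians over 21 and 151 bins, the replicate number as a block, and each library left out in turn. Segment slopes, the profile by distance, the summed replicates and a correction for collapsed reads (2000 possible start positions per bin) were added after the data were seen.

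The tests were tried on simulated data with known answers. Of 50 bins changed 1.25-fold, 82% were recovered in the single-bin test and 80% in the local test over 3995 bins, and 100% of those changed 1.5-fold, 2-fold or 0.5-fold; unchanged bins were called in 0.369% and 0.29% of cases. All simulated changes of 1.1-fold, 1.2-fold and 0.8-fold in the 41 windows were recovered, with 3.45% of unchanged windows called. These counts were simulated bin by bin, with independent noise (dispersion 0.001) around a profile shared by all libraries. They lack the differences in profile between replicates, so the rates for windows and single bins do not carry over to the real ones (common dispersion 0.000483 and 0.000243). The local test takes each library's profile out, but its real common dispersion, 9.77e-05, was also unlike the simulated one. Simulated arm slopes were recovered within 0.0144 per Mb and simulated log2 ratios within 0.022, while the simulated terminus was found 15.5 kb from its true position.

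The gene table used as reference belongs to another strain, 168, and another build than PY79, and no position was carried over from it. Gene lists and the copy number of *amyE*, native *ccrZ* and the promoter's regulator were therefore not analysed here, and the labels were not checked by the targeted gene. Positions are those of the deposited PY79 table, counted from 1, without gene annotation.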

Results

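Genomic DNA from 6 samples of *Bacillus subtilis* PY79, a prototrophic laboratory strain, was sequenced, and reads were counted in bins of 1 kb along the chromosome. In a growing culture, sequences near the replication origin are present in more copies than sequences near the terminus, so the count per bin along the chromosome (the marker frequency profile) reads out how replication stands in the population. All cells lacked native *ccrZ*, which encodes a cell cycle regulator first described in pneumococci, and carried a xylose-inducible copy at *amyE*, a standard integration site. In 3 libraries this copy was the unaltered gene (the ccrZ group), and in 3 it was the D166A variant (the ccrZ-D166A group). Cultures were grown at 30 °C, received 0.1% xylose at an optical density of 0.2 and were harvested between 0.65 and 0.9. The growth protocol calls the cells WT, although both genotypes lack native *ccrZ*; groups follow the genotype label. Total counts were 932555, 1126671 and 1202671 in ccrZ replicates 1, 2 and 3, and 1266560, 1286983 and 1081402 in ccrZ-D166A replicates 1, 2 and 3. The median bin held between 180 and 308 counts per library, for which counting error alone gives a coefficient of variation between 5.70% and 7.45%. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Uninduced cells and cells with native *ccrZ* were not analysed here, so each group is described relative to the other.

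The first comparison asked whether the D166A substitution changed the copy number of the origin relative to the terminus in cells overexpressing *ccrZ*. Cells overexpressing unaltered *ccrZ* carried 6.55 ± 0.198 (SD, n = 3) origin copies per terminus copy, and cells overexpressing *ccrZ*-D166A carried 2.94 ± 0.0847 (SD, n = 3). The ratio of the geometric means was 2.23. The lowest ccrZ library, replicate 3, stood at 6.34 and the highest ccrZ-D166A library, replicate 1, at 3.02, so the groups did not overlap. On the log2 scale the ratio was 2.71 ± 0.04 in the ccrZ group and 1.55 ± 0.04 in the ccrZ-D166A group (SD, n = 3), a difference of -1.16 with a standard error of 0.03. The two-sided exact permutation test over the 20 assignments of the libraries gave p = 0.1, the smallest value it can give for 3 libraries against 3, so this test cannot reach 0.05 here. The origin was taken as the first base of the PY79 sequence, and the terminus as the centre of the bin from 1979001 to 1980000, where the profile summed over all 6 libraries was lowest. The median bin of the terminus window held between 86.0 and 174.0 counts.

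**Figure D1:**
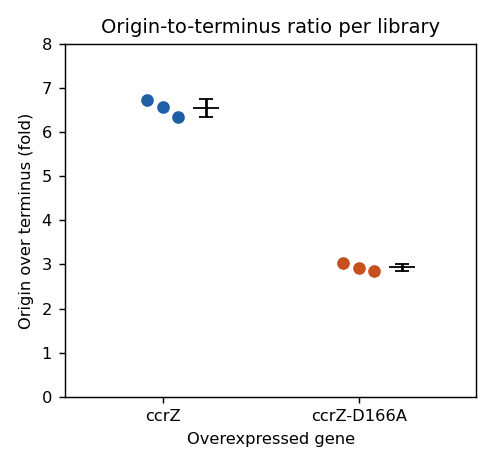
Origin-to-terminus ratio (fold, vertical axis) of each library, by overexpressed gene (horizontal axis). Points are libraries, and the black bars beside them show the mean and SD of the 3 libraries, 6.55 ± 0.198 for ccrZ and 2.94 ± 0.0847 for ccrZ-D166A.

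The second comparison asked how steeply copy number declined along each chromosome arm and whether the 2 arms behaved alike. Over the whole right arm, the log2 count per bin dropped by 1.36 ± 0.06 per Mb in the ccrZ group and by 0.78 ± 0.0038 per Mb in the ccrZ-D166A group (SD, n = 3). On the left arm the drop was 1.37 ± 0.04 and 0.79 ± 0.0041 per Mb. The group difference was -0.57 per Mb on the right arm and -0.58 per Mb on the left, each with p = 0.1 in the two-sided exact permutation test, again the smallest possible. The difference between the arms, right minus left, was -0.01 ± 0.02 per Mb in the ccrZ group and -0.01 ± 0.0021 in the ccrZ-D166A group (SD, n = 3; exact permutation p = 0.7). The group difference in this quantity was 0.0049 per Mb, and 0.0299 with the terminus set opposite the origin (exact permutation p = 0.1). Such slopes average over each arm and can hide differences along it. In segments of 400 kb, fitted after the data were seen, the drop from 1200 to 1600 kb was smaller on the right arm. In the ccrZ group it was 0.95 ± 0.04 against 1.23 ± 0.04 per Mb (SD, n = 3). In the ccrZ-D166A group it was 0.84 ± 0.04 against 1.02 ± 0.07. Within 400 kb of the origin the ccrZ mean was larger on the right arm, 1.72 against 1.43. The arms were not tested against each other by segment. The profile minimum lay at 1989.8 ± 22.2 kb in the ccrZ group and at 1990.5 ± 7.94 kb in the ccrZ-D166A group (SD, n = 3, exact permutation p = 1.0). A shift of the terminus was thus not detectable within a spread of this size. In simulated data the minimum of the profile summed over all libraries was found 15.5 kb from the true terminus. The error for single libraries was not simulated.

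Copy number was then followed by distance from the origin, relative to the terminus window of the same library, at distances chosen after the data were seen. At 250 kb on the right arm it was 4.97 ± 0.354 in the ccrZ group and 2.75 ± 0.0427 in the ccrZ-D166A group (SD, n = 3), a log2 difference of -0.85. At 500 kb the corresponding values were 3.52 ± 0.238 and 2.30 ± 0.0556, and at 1000 kb they were 2.09 ± 0.0377 and 1.79 ± 0.0336. At 1750 kb they were 1.21 ± 0.0014 and 1.19 ± 0.0385, a log2 difference of -0.03 (exact permutation p = 0.4). The left arm gave 5.28 ± 0.211 and 2.83 ± 0.0679 at 250 kb, and 1.27 ± 0.0349 and 1.24 ± 0.0250 at 1750 kb (exact permutation p = 0.3). At all other distances examined, from 50 to 1500 kb on either arm, the permutation test gave p = 0.1.

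**Figure D2:**
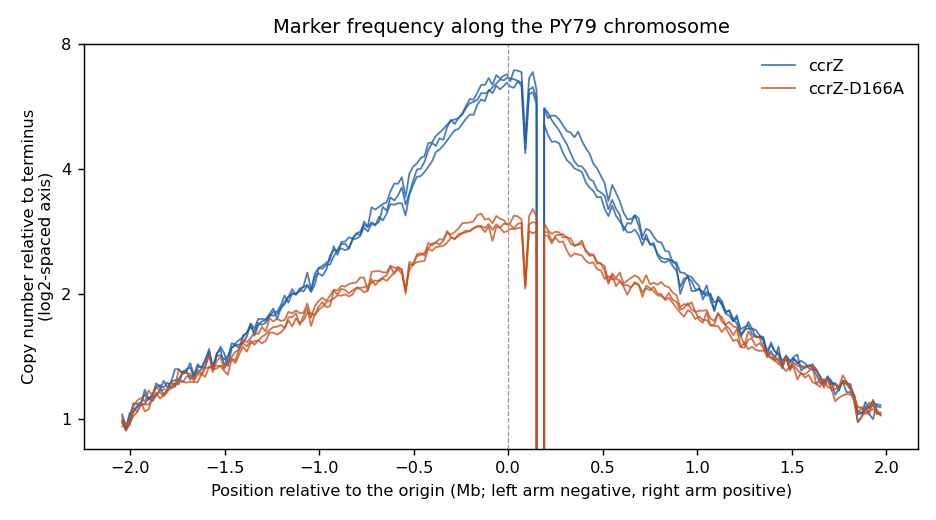
Copy number relative to the terminus window (vertical axis, log2-spaced) against position relative to the origin (horizontal axis, Mb), as medians over stretches of 20 kb. Each line is a library; the ccrZ libraries peak near 6.55 and the ccrZ-D166A libraries near 2.94, and the narrow dips right of the origin are stretches with bins at 0 in every library.

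The decline was not uniform, and the groups differed most near the origin. The group difference in drop per Mb within 800 kb of the origin exceeded that beyond 1600 kb by -0.93 (SE 0.0563, n = 3 per group; exact permutation p = 0.1, the smallest possible). Slopes were fitted in segments of 400 kb with limma, an analysis added after the data were seen. Within 400 kb of the origin the log2 count on the right arm dropped by 1.72 ± 0.47 per Mb in the ccrZ group and by 0.38 ± 0.26 per Mb in the ccrZ-D166A group (SD, n = 3). The difference was -1.33 per Mb (95% interval -1.96 to -0.70, limma, adjusted p = 0.00346). This right-arm fit included bins beside stretches with almost no counts, at 0.11 to 0.64 of their local level on average over the libraries. Further low bins lay near its outer end. Segments were not refitted without such bins, which may affect the slopes of both groups there. On the left arm the drops were 1.43 ± 0.20 and 0.40 ± 0.14 per Mb, a difference of -1.03 (95% interval -1.33 to -0.72, limma, adjusted p = 0.000652). From 400 to 800 kb the difference was -0.94 per Mb on the right arm and -0.89 on the left, and from 800 to 1200 kb it was -0.53 and -0.62. From 1200 to 1600 kb the left arm differed by -0.21 (limma, adjusted p = 0.0112), and the right arm gave -0.11 (adjusted p = 0.0648). Beyond 1600 kb the differences were -0.07 on the right arm (95% interval -0.19 to 0.06; limma, adjusted p = 0.239) and -0.09 on the left (95% interval -0.22 to 0.05; adjusted p = 0.179). In total 7 of 10 segments passed the adjusted threshold of 0.05, all with the smaller drop in the ccrZ-D166A group. These intervals rest on the spread between the 3 libraries of each group, with the variance of each segment drawn by limma toward those of the other segments.

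**Figure D3:**
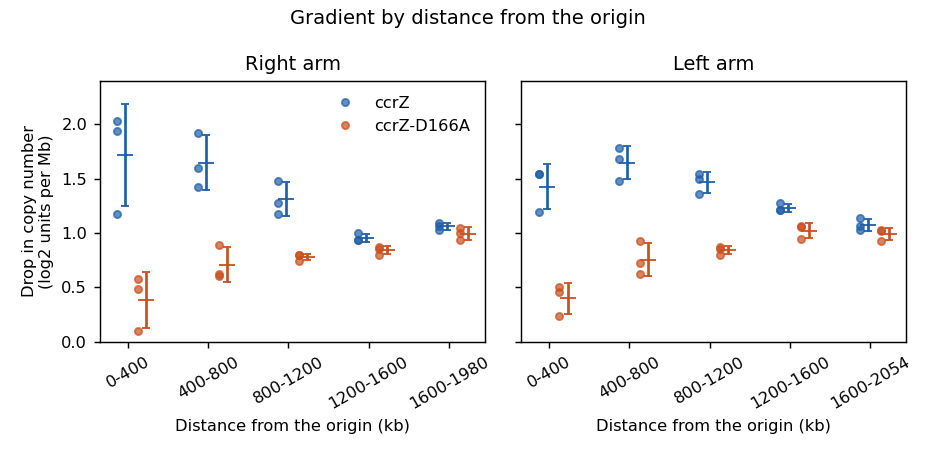
Drop in log2 copy number per Mb (vertical axis) in consecutive segments of each arm by distance from the origin (horizontal axis, kb). Points are libraries and bars show the mean and SD of 3 libraries; within 400 kb of the origin on the right arm the means are 1.72 for ccrZ and 0.38 for ccrZ-D166A, and beyond 1600 kb the groups lie close together.

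Regional copy number was compared in 41 consecutive windows of 100 kb. Relative to the library as a whole, the ccrZ-D166A group was lower in the windows around the origin and higher in those around the terminus. With TMM factors, edgeR's quasi-likelihood test called 21 windows higher in the ccrZ-D166A group, a continuous stretch from 900001 to 3000000. It called 18 windows lower, from 1 to 800000 and from 3100001 to the end of the sequence, and left 2 windows uncalled. The lowest log2 values were -0.87 in the window starting at 4000001, which is shorter than the others (SE 0.0172, adjusted p = 3.01e-18), -0.84 in the window from 1 to 100000 (SE 0.0378, adjusted p = 1.27e-12), and -0.80 from 3900001 to 4000000 (SE 0.0445, adjusted p = 1.55e-11). In the window from 1 to 100000, the ccrZ group held 49450 ± 1510 CPM, scaled to total counts, and the ccrZ-D166A group 32205 ± 675 (SD, n = 3), for which the log2 value with total counts is -0.62. The highest values were 0.29 from 2000001 to 2100000 (SE 0.0203, adjusted p = 1.38e-10), 0.28 from 1800001 to 1900000 (SE 0.0192, adjusted p = 1.00e-10) and 0.27 from 1900001 to 2000000 (SE 0.0212, adjusted p = 7.73e-10). The direction around the terminus depended on the scaling, since such values are relative. Scaled to the terminus window, 0 windows were higher and 34 lower, and those 3 windows gave -0.0048, -0.0134 and -0.0268 (adjusted p = 0.81, 0.509 and 0.194); with total counts 27 were higher and 13 lower. The share of higher windows among those called was 53.85% with TMM factors, 67.5% with total counts and 0.0% with terminus scaling. The median log2 value over all windows was 0.06, 0.29 and -0.23 in these scalings.

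At the resolution of single bins, 3995 bins had at least 10 counts in at least 3 libraries. Of these, edgeR's quasi-likelihood test called 1530 higher and 1365 lower in the ccrZ-D166A group, following the same gradient, so neighbouring bins are not independent. Among bins called by edgeR 52.85% were higher with TMM factors, 46.26% with median-of-ratios factors, 71.62% with total counts and 0.09% with terminus scaling. DESeq2, which also scales by median-of-ratios factors, gave 28.57%. The largest decreases lay just left of the origin. The bin from 4024001 to 4025000 held 664 ± 12.04 CPM in the ccrZ group and 388 ± 25.1 in the ccrZ-D166A group (SD, n = 3), scaled to total counts. Its log2 value was -0.77 with total counts and -0.96 with TMM factors (SE 0.0548, edgeR adjusted p = 1.19e-39). The bins starting at 4026001 and 4010001 gave -0.92 and -0.91 with TMM factors. The largest increases lay in the bins starting at 1989001, 1456001 and 2082001, with 0.56, 0.56 and 0.55. With terminus scaling these became 0.23, 0.23 and 0.22 (edgeR adjusted p = 0.0603, 0.0385 and 0.061), so the first and the last were no longer called.

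Local copy number changes, such as a deletion or a duplication in some cells of 1 group, were sought by comparing each bin with the running median of 51 bins around it in the same library. A change that covers most of these 51 bins moves the running median with it, so longer changes could not be called in this way. The simulated changes were of single bins only. Of 3995 bins, edgeR's quasi-likelihood test called 0 higher and 2 lower in the ccrZ-D166A group. An unadjusted p under 0.05 was reached by 154 bins, a share below the 0.05 that would arise with no bin changed. The 2 bins adjoin, from 2878001 to 2880000 on the left arm. The first held 1.61 ± 0.154 times its local median in the ccrZ group and 1.22 ± 0.105 times in the ccrZ-D166A group (SD, n = 3), a log2 difference of -0.39 (SE 0.0635, adjusted p = 0.000265). The second gave 1.41 ± 0.149 and 1.11 ± 0.0594, a log2 difference of -0.34 (SE 0.0657, adjusted p = 0.00618). The call was lost with DESeq2, which called 0 bins in either direction (18 with an unadjusted p under 0.05; adjusted p = 0.163 for the first bin), with a running median over 21 bins (adjusted p = 0.312) and without ccrZ replicate 2 (adjusted p = 0.0948). Without ccrZ-D166A replicate 1, and likewise without replicate 3, 1 bin was called.

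**Figure D4:**
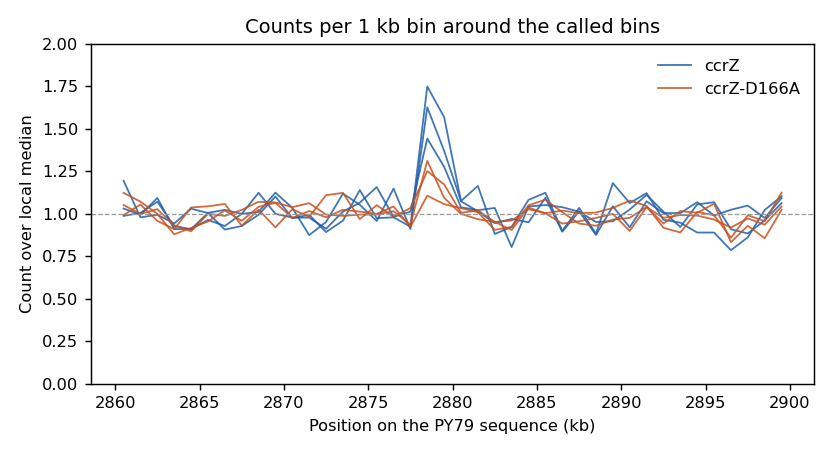
Count per bin over the local median of 51 bins (vertical axis) against position on the PY79 sequence (horizontal axis, kb), with a line for each library. The bins from 2878001 to 2880000 stand above 1 in all 6 libraries, on average at 1.61 times the local median in the ccrZ group and 1.22 times in the ccrZ-D166A group for the first of them.

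Some stretches of the chromosome carried almost no counts in any library. In 11 blocks of 1 to 4 bins, each bin held at most 2 counts over all 6 libraries, and 38 of the 4034 bins (0.942%) were at 0 throughout. Of these blocks, 7 lie within 200 kb to the right of the origin, the first from 10001 to 14000. Because the blocks are shared by both groups, they give no difference between them, and copy number there was not measured.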

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

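The correction for collapsed reads, the summed replicates and every test of segment slopes were chosen after the data were seen; the other alternatives were fixed before. The lower origin-to-terminus ratio in the ccrZ-D166A group kept its direction in every alternative run, with log2 differences from -1.27 to -1.12, and so did both arm slopes, from -0.61 to -0.55 (right) and -0.62 to -0.57 (left). With each library left out in turn the ranges were -1.18 to -1.12, -0.60 to -0.55 and -0.61 to -0.57, and 0.0042 to 0.0178 for right minus left (exact permutation p = 0.1 without ccrZ replicate 2). Right minus left rose from 0.0049 to 0.0302 with Theil-Sen slopes (exact permutation p = 0.4) and to 0.0299 with the terminus opposite the origin (p = 0.1, the smallest possible); the cause was not tested. The -1.27 came from the correction for collapsed reads, with mean ratios of 7.74 and 3.22. The difference in terminus position, where no shift was detectable, changed sign when ccrZ replicate 2 or 3, or ccrZ-D166A replicate 2 or 3, was left out (-6 to 13.5 kb, exact permutation p from 0.2 to 1.0); the cause was not tested.

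Scaling set the direction of many calls: terminus scaling gave 0 higher and 34 lower windows and 2 higher and 2279 lower bins, and total counts gave 2420 higher bins. The windows at 2000001, 1800001 and 1900001 then read -0.0048, -0.0134 and -0.0268, since this scaling lowers the log2 value of all windows alike. DESeq2 called 516 bins higher and 1290 lower. With median-of-ratios factors, the scaling that DESeq2 uses, edgeR's test called 1232 higher and 1431 lower. Scaling alone therefore does not give the 516, and what else does was not tested. Windows of 50 kb gave 42 higher and 35 lower and windows of 200 kb gave 11 and 9, sums of 5 bins 397 and 319, and sums of 10 bins 204 and 163, as fewer or more units were tested. Without single libraries the counts were 21 and 18 windows throughout, 1063 to 1330 bins higher and 1303 to 1379 lower. The 2 local bins became 0 with DESeq2 and with a running median over 21 bins, and 0 to 2 without single libraries; the first bin ranged from -0.47 to -0.32, with adjusted p from 0.000108 to 0.312 over its alternatives, and the cause was not tested. Segment slopes gave 7 calls without any single library and 9 with segments of 300 kb. Without single libraries, the differences beyond 1600 kb ran from -0.0926 to -0.0353 per Mb (right) and from -0.1121 to -0.0545 (left). Both were nearest 0 without ccrZ-D166A replicate 2.

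Of the same-numbered libraries, only those of replicate 1 deviated together (r = 0.394, -0.462 and -0.193), and not every library correlated best with its own number (replicate 1 of ccrZ with replicate 2 of ccrZ-D166A: r = 0.52), so the numbers were not taken to pair samples. With the replicate block, edgeR called 21 and 18 windows, 1537 and 1361 bins and 0 and 2 local bins, and the log2 ratio difference of -1.16 had a sign-flip p of 0.25, the smallest possible. The alternatives at the annotated terminator gene, the gene lists and the landmark copy numbers were not run. Depth limits single bins, for which counting error alone gives a coefficient of variation between 5.70% and 7.45%.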

Other observations

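All tests in this part were chosen after the results were seen. The maximum of the running median lay 25.5, 0.5 and 22.5 kb from the origin in ccrZ replicates 1, 2 and 3, and 149, 26.5 and 143 kb from it in ccrZ-D166A replicates 1, 2 and 3, to the left in the first and the last. The ccrZ-D166A profile was nearly flat there. Its windows starting at 3800001 and 3900001 held 38767 ± 542 and 38436 ± 822 CPM (SD, n = 3). Empty blocks right of the origin also lower the running median on that side, so these maxima do not locate a shifted peak. Within 800 kb of the origin, averaged over the arms, the log2 count dropped by 1.73 ± 0.0969 per Mb in the ccrZ group and by 0.717 ± 0.0236 in the ccrZ-D166A group (SD, n = 3). Beyond 1600 kb the values were 1.07 ± 0.0397 and 0.992 ± 0.0563. The gradient was thus steeper near the origin than near the terminus in each ccrZ library, by 0.657 ± 0.0606 per Mb on average, and shallower near the origin in each ccrZ-D166A library, where the same difference was -0.275 ± 0.0765 per Mb.

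A few bins were low in every library without lying next to an empty block. The bin from 328001 to 329000 stood at 0.545 ± 0.0113 of its local median in the ccrZ group and 0.529 ± 0.0155 in the ccrZ-D166A group (SD, n = 3; exact permutation p = 0.2). The spread between replicates around their own profiles was 0.850 of the Poisson expectation in the ccrZ group and 0.873 in the ccrZ-D166A group, with slopes against the count of -0.246 ± 0.0855 and -0.615 ± 0.146 per 1000 counts (SE).

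The lower origin-to-terminus ratio in the ccrZ-D166A group was set against depth, position-dependent bias and growth state. With the log2 total count of each library as a covariate the log2 difference was -1.15 (SE 0.0454, 95% interval -1.292 to -1.003), which argues against unequal depth as the whole cause. A bias from base content or mappability would part neighbouring bins as well; with the gradient taken out, the variance of the group difference between bins was 0.923 (SE 0.028) of that expected from counting, against 0.875 for the spread between replicates (excess 0.048, SE 0.0247), and without the base content of the bins, not used here, such a bias stays open. A different growth state at harvest cannot be told apart from the substitution, since a density of its own is stated for 0 of the 6 libraries and a single range for all. The substitution itself, which the design names, stays among the open explanations and was not tested apart from growth state.

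The second pattern is the concentration of the group difference near the origin. A uniform change in fork passage relative to doubling time would alter all segments alike, but the group difference was larger within 800 kb of the origin than beyond 1600 kb by -0.93 per Mb (SE 0.0563). Collapsing of reads with the same start, which lowers the highest counts, would have to be stronger in the ccrZ-D166A group; with each group corrected by the fall of its replicate spread with the count, the same quantity was -0.962 (SE 0.0626), and -0.848 (SE 0.0701) with both slopes moved by 2 SE in favour of collapsing, which argues against it as the whole cause. Forks started recently in the ccrZ group, which had not reached the terminus at harvest, are a candidate explanation and would leave the outer part equal. The difference there was -0.0768 per Mb (SE 0.0398, n = 3 per group, exact permutation p = 0.1, the smallest possible), with every ccrZ library above every ccrZ-D166A library. This goes against an equal outer part but is under 2 standard errors from 0. The lowest drop, 0.928, was that of ccrZ-D166A replicate 2. Replicates 1 and 3 stood at 1.0125 and 1.035, close to the lowest ccrZ library at 1.045. The candidate stays open, as do slower forks near the origin, which were not tested.

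The third pattern is the excess of counts in the bins from 2878001 to 2880000, larger in the ccrZ group. The 2 bins summed differed by -0.37 on the log2 scale (SE 0.0983), but they were picked for this difference, so equal extra copies in both groups stay open. Reads from a copy of the sequence closer to the origin could also give the pattern. The level around the low bin at 328001 was taken for that copy. The share of the 2 bins read at that level, in place of their own, would be 0.397 ± 0.0549 in the ccrZ group. In the ccrZ-D166A group it would be 0.323 ± 0.134 (SD, n = 3), a difference of -0.0735 (SE 0.0836). A copy read in addition to the local sequence would give other shares and was not tested. The level of the copy was picked from the data and the test is weak. Replicate 1 of ccrZ-D166A stood at 0.174, and replicates 2 and 3 at 0.434 and 0.361. All cells lacked native *ccrZ* and carried a copy at *amyE*. Without annotation, whether the 2 bins or the low bin hold sequence of the construct was not tested. An exchange of reads with the low bin itself, as the whole reason for its low count, would take 0.820 ± 0.0496 of its reads in the ccrZ group (SD, n = 3) but 1.402 (SE 0.0348) in the ccrZ-D166A group, above the maximum of 1; a read filter would lower that bin too, so a partial exchange stays open.

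The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Each other split mixes libraries of both groups on each side, so the group difference widens the spread within its sides. This alone holds down the calls for windows, single bins and segment slopes, so the other splits give no rate of false calls. In edgeR's tests, 1 split, the real one, gave as many as 39 called windows (highest other 0) and 1 gave as many as 2895 called bins (highest other 1). For segment slopes 1 split gave as many as 7 calls (highest other 0). For local bins 2 splits gave as many as 2 calls, the real one and another with 2.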
